A study of Mus musculus with 8 samples.

How the data were processed

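Total RNA of thymocytes from wild-type mice of 2 strains, B6 and BALB, was sequenced by the submitters in 8 libraries, 2 of sorted DP thymocytes and 2 of whole thymocytes from each strain. Strain was taken from the library names, which give no substrain. Per the labels, DP thymocytes were CD4+ CD8+ CD69-negative cells with low or intermediate H57 staining sorted on a FACSAria III, and libraries were made with the TruSeq RNA Sample Prep Kit v2, which does not keep the strand. Per the submitters' processing notes, reads were aligned with HISAT2 2.2.0 to mm10 (GRCm38), counted with HTSeq, and compared with DESeq2 1.42.1. HTSeq's version, the gene annotation, the read length and the read filters are not given in the sources used here. The deposited files hold raw whole-number counts per gene symbol, 1 file per library, with HTSeq's totals of reads outside genes in the last lines.

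The files list 23420 gene symbols, of which 23260 were matched in the reference annotation. They list no symbols starting with mt- and none of the T cell receptor constant genes Trac, Trbc1 and Trbc2, so those are not analysed here. Each file accounts for 11214574 to 19602652 reads, of which 22.6% to 30.8% were in genes, 43.3% to 48.9% in no gene, 12.8% to 21.2% not aligned and 10.1% to 11.9% not unique. Counts in genes ranged from 2632083 to 5974684 per library.

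Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 4 groups, which left 11409 genes, while 6025 genes with a count were not tested. Libraries were scaled by the trimmed mean of M values (factors 0.957 to 1.05). A model with 1 coefficient per group was fitted by quasi-likelihood, and the common biological coefficient of variation was 0.114. Contrasts were BALB over B6 in DP and in whole thymocytes, whole over DP thymocytes in B6 and in BALB, and the interaction, (BALB minus B6 in whole) minus (BALB minus B6 in DP). An additive model of strain and population gave the comparisons over both populations and over both strains. Genes at a Benjamini-Hochberg adjusted p under 0.05 were called. Errors of log2 fold changes are standard errors from the fit and those of CPM are standard deviations over 2 libraries. The replicate numbers were not used to pair libraries.

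Where all libraries of a group had no counts, the fold is a floor computed with 3 counts over the group, and with 1 to 3 counts a ratio with an exact 95% counting interval is given. Tests were made against 31 fixed lists with 617 entries, some genes being on more than 1 list, written before the data were examined, as were the comparisons, the rule for naming genes and the alternatives except 2. Of the entries 606 were found, 5 of them under an older symbol. The lists were DP thymocyte, DN thymocyte, TCR signal and positive selection, Mature thymocyte and egress, CD4 lineage, CD8 lineage, Regulatory T cell, Innate-like NKT cell, Gamma-delta T cell, IL-4 response and memory-like CD8, B cell, Myeloid and dendritic cell, Thymic epithelial cell, Erythroid, Endothelial and mesenchymal, NK receptor complex, Cell cycle, Interferon response, MHC class I region, TCR signalling machinery, Recombination and DNA end joining, Apoptosis, p53 target, Immediate early, Heat shock, Cholesterol synthesis, Glycolysis, Oxidative phosphorylation, Cytosolic ribosomal protein, Strain-polymorphic and Sex-linked genes. Lists share members, among them Rag1, Rag2 and Dntt in the DP and the recombination list, Cd4, Cd8a and Cd8b1 in the DP and a lineage list, and Eomes, Il2rb and Bcl2 in the IL-4 list and another. Each list with at least 5 tested genes was tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the data, and fry, were alternatives. Counts adjusted over the list alone use the same p-values adjusted within the list.

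Genes were named by a rule. In each of the 4 simple comparisons it took the 8 called genes with the largest change in each direction among those whose groups did not overlap and whose mean was at least 5 CPM in the higher group, and up to 4 members with the smallest p of each list that was called or had a called member. For the interaction and the comparisons over both it took up to 6 genes per direction with the smallest p, and 25 genes were always eligible. Principal components were computed on log2 CPM, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

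Alternatives were DESeq2 1.42.0 size factors, upper-quartile scaling, no filter, a strict filter (1 CPM in 2 libraries and a mean count of 50), the DESeq2 Wald test, limma-voom, robust empirical Bayes, glmTreat against a fold of 1.5, a replicate block, thinning to the smallest library, leaving out strain-variable gene families, only the 4 libraries compared, the average of the 2 simple contrasts for the comparisons over both, an overlap at an adjusted p of 0.01, and leaving out each library in turn. Leaving out chromosomes X and Y, and leaving out both libraries that stood apart, were added after seeing the data. The steps were tested on simulated counts with the depths of these libraries and 100 genes changed at each of 2 folds. At 2-fold 64.6% of changed genes were recovered for strain in DP, 73.5% for strain in whole thymocytes, 75.3% for population in B6, 79.2% for population in BALB and 40.0% for the interaction. At 4-fold the shares were 92.9%, 97.0%, 99.0%, 91.9% and 82.3%, and 2, 6, 11, 7 and 8 unchanged genes were called. The simulation gave every group the same dispersion for a gene. In the data the replicates of BALB DP differed more (Pearson chi-square per degree of freedom 18.3) than those of the other groups (1.62 to 4.35). The recovered shares and the calls of unchanged genes do not cover such unequal spread. In the simulation a Cell cycle list raised 1.5-fold was called with an estimated correlation (adjusted p = 0.00356). At the preset correlation, which the list calls use, 2 lists were called, the Cell cycle list and the Apoptosis list, which had not been changed. Protein levels, chromatin, splicing and sequence variants in reads are not analysed here.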

Results

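RNA sequencing measured the transcripts of thymocytes, the developing T cells of the thymus, from wild-type mice of 2 strains that the labels call B6 and BALB. From each strain, DP thymocytes and whole thymocytes were sequenced, with 2 libraries in each of the 4 groups and 8 libraries in all. DP thymocytes carry both CD4 and CD8 and make up the stage at which the T cell receptor alpha chain is rearranged and tested. The sort for them took cells without CD69, an early activation marker, and with low or intermediate staining by H57, an antibody to the T cell receptor beta chain. Whole thymocytes hold every stage, from CD4-negative and CD8-negative (DN) precursors to mature single-positive cells, together with the few other cells of the organ. The labels do not say whether the replicates of a group came from separate animals, so they may be technical. In BALB whole thymocytes, replicate 1 had 0 counts of the Y-linked Ddx3y and 12313 of Xist, and replicate 2 had 725 and 203. This argues against repeat libraries of 1 sample in that group.

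The files held between 2632083 and 5974684 counts in genes per library, and 13052 to 15231 genes had a count in a library. In order of replicate, the B6 DP libraries held 3274924 and 4560030 counts, the B6 whole thymocyte libraries 3907143 and 4069166, the BALB DP libraries 5974684 and 2632083, and the BALB whole thymocyte libraries 3952234 and 3879807. BALB DP replicate 1 stood apart in composition, with 3.14% of its counts in the ribosomal RNA precursor gene Rn45s against 5.11% to 8.35% in the other libraries. Histone genes held 2.52% of its counts and 1.97% in BALB DP replicate 2, against 1.15% to 1.41% outside that group, so both BALB DP libraries were high. BALB whole thymocyte replicate 1 stood apart in sex-linked genes, with 12313 counts of Xist and no counts of the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y. The first principal component, 52.1% of the variance, separated whole from DP thymocytes, and the second, 26.4%, separated the strains. Pearson correlations of log2 CPM, counts scaled to library size, across genes, which are not independent replicates, were 0.977 to 0.988 within groups and 0.909 to 0.960 between groups. Intervals and floors given for single genes cover counting error only.

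**Figure D1:**
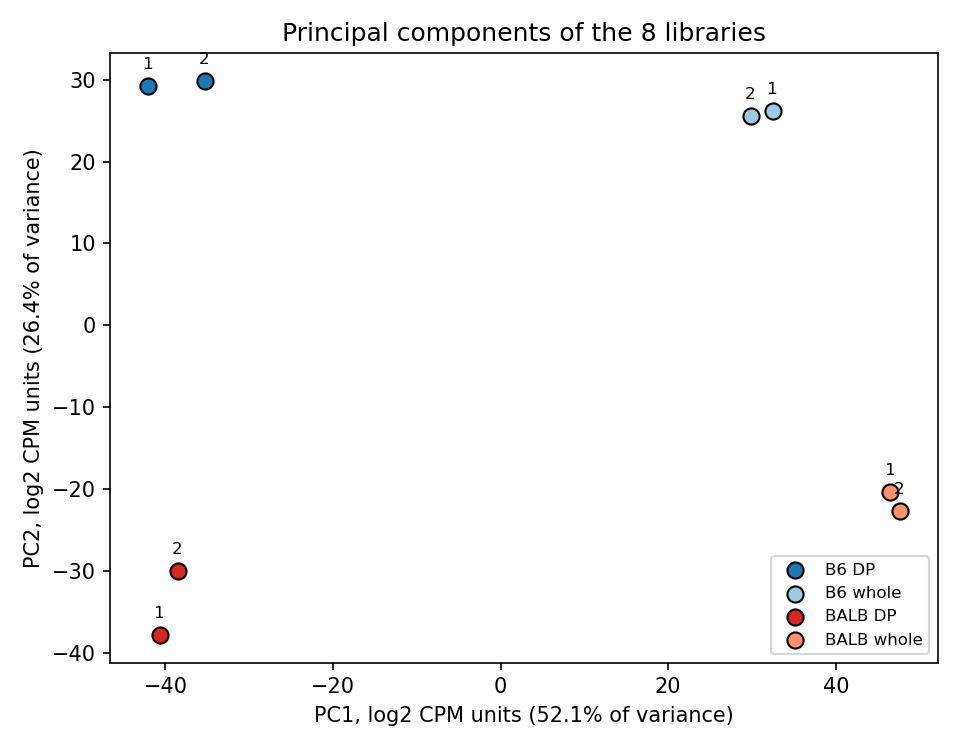
Each point is a library placed by its first 2 principal components of log2 CPM, coloured by group and numbered by replicate. Whole thymocytes lie to the right of DP thymocytes on the first component (52.1% of the variance), and BALB lies below B6 on the second (26.4%).

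The comparison of whole thymocytes with sorted DP thymocytes within B6 asks which transcripts differ between the sorted stage and the whole organ's thymocytes. Genes of mature thymocytes were much more abundant in whole thymocytes. S1pr1, the receptor that guides mature thymocytes out of the thymus (chromosome 3, 115710433 to 115715055; all positions are in mm10), had no counts in the B6 DP libraries and 29.2 ± 1.02 CPM (mean ± SD, n = 2) in whole thymocytes, at least 72.2-fold higher. Gimap4, a GTPase of mature T cells, rose by a log2 fold change of 6.92 ± 0.28 (SE), Ccr7, a chemokine receptor that directs cells to the medulla, by 3.57 ± 0.35, and the survival gene Bcl2 by 2.72 ± 0.15. Of the 21 Mature thymocyte and egress genes tested, 13 rose, none fell and 8 did not pass, or 15 rose adjusted over the list alone (camera adjusted p = 3.91e-36; adjusted p = 0.0172 with an estimated correlation). Genes induced by T cell receptor signals moved the same way. The sort left out cells with CD69 or high H57 staining. A rise of these genes and of mature thymocyte genes in whole thymocytes was therefore largely set by the sort. Cd5, a negative regulator whose level follows receptor signal strength, rose from 77.6 ± 7.34 to 164 ± 2.04 CPM, Cd69 by a log2 fold change of 1.61 ± 0.17, the orphan receptor Nr4a1 by 2.51 ± 0.22 and Itm2a, a gene induced during positive selection, by 3.46 ± 0.17. Among the 18 TCR signal and positive selection genes, 13 rose, 1 fell and 4 did not pass (14 and 1 adjusted over the list alone; camera adjusted p = 2.01e-26; adjusted p = 0.0172 with an estimated correlation). Among the genes named here the largest adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.000313 (Cd5).

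The genes of the DP stage fell in B6 whole thymocytes, by less. Rag1, which makes the recombinase that cuts receptor gene segments (chromosome 2, 101638252 to 101649532), was at 9842 ± 532 CPM in DP and 5627 ± 178 CPM in whole thymocytes, a log2 fold change of −0.88 ± 0.076. Arpp21 changed by −0.61 ± 0.076, the repressor Bcl6 by −0.67 ± 0.094, Cd4 by −0.61 ± 0.10 and Cd8a by −0.53 ± 0.079. Of 20 DP thymocyte genes 14 fell, none rose and 6 did not pass (16 fell adjusted over the list alone; camera adjusted p = 1.55e-11; adjusted p = 0.0419 with an estimated correlation). Among 16 Recombination and DNA end joining genes, 6 fell and none rose, or 7 fell adjusted over the list alone (camera adjusted p = 0.0132; adjusted p = 0.199 with an estimated correlation). The largest fall among genes with counts in both groups was that of Jun, an immediate early transcription factor (chromosome 4, 95049036 to 95052222), from 119 ± 20.4 to 7.36 ± 2.80 CPM, −4.08 ± 0.24. Mogat1, an acyltransferase, was at least 19.4-fold lower. Of 15 Immediate early genes 4 fell and 2 rose (5 and 3 adjusted over the list alone; camera adjusted p = 0.0208, downward; adjusted p = 0.122 with an estimated correlation). Myc was among those that rose, by 1.83 ± 0.18. Without B6 whole thymocyte replicate 2 the camera call of the Immediate early genes ended, at an adjusted p of 0.0938. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p of at most 0.00210 (Cd4) for the genes named here.

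Genes of CD4, regulatory, innate-like and gamma-delta T cells were called upward as lists in B6 whole thymocytes, and those of the CD8 lineage were not. Zbtb7b, the transcription factor of the CD4 lineage, had a ratio of 173 (95% counting interval 30.7 to 6866) between whole and DP libraries, and Cd40lg, the helper ligand, was at least 31.0-fold higher. Runx3, the factor of the CD8 lineage, rose by 1.30 ± 0.18. Il2rb, a receptor subunit for interleukins 2 and 15, was at least 55.8-fold higher, and Zbtb16, the transcription factor of innate-like T cells, was at least 15.2-fold higher. Of 9 CD4 lineage genes 5 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 3.11e-05; adjusted p = 0.0611 with an estimated correlation). Of 9 CD8 lineage genes 3 rose and 2 fell (3 and 3 adjusted over the list alone), and camera made no call (0.113). Among 13 Regulatory T cell genes 7 rose and none fell, also adjusted over the list alone (camera adjusted p = 2.01e-11; adjusted p = 0.0329 with an estimated correlation). Among 14 Innate-like NKT cell genes 8 rose and none fell (11 adjusted over the list alone; camera adjusted p = 3.78e-12; adjusted p = 0.0172 with an estimated correlation). The Gamma-delta T cell genes held 3 that rose and 1 that fell of 7 (5 and 1 adjusted over the list alone; camera adjusted p = 0.00930; adjusted p = 0.10 with an estimated correlation). DN precursor genes were also higher, with Il2ra, a receptor chain of DN and regulatory cells, up by 2.64 ± 0.21, and 7 of 14 DN thymocyte genes rose with none falling (9 adjusted over the list alone; camera adjusted p = 6.27e-09; adjusted p = 0.0419 with an estimated correlation). The largest adjusted p of these genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 0.00350 (Zbtb16).

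Transcripts of cells that are not thymocytes, and of interferon-responsive and antigen-presentation genes, rose in B6 whole thymocytes as well. Cd74, the invariant chain of MHC class II, rose by 3.73 ± 0.23, and Ctss, a protease of antigen-presenting cells, had a ratio of 100.4 (95% counting interval 27.5 to 834). Of 22 Myeloid and dendritic cell genes 17 rose and none fell (19 adjusted over the list alone; camera adjusted p = 3.31e-43; adjusted p = 0.00721 with an estimated correlation). The keratin Krt8 was at least 10.8-fold higher and the collagen gene Col3a1 at least 11.8-fold higher. Among 11 Thymic epithelial cell genes 7 rose and none fell (10 adjusted over the list alone; camera adjusted p = 3.41e-08; adjusted p = 0.0419 with an estimated correlation). Of 9 B cell genes 4 rose, with the same number adjusted over the list alone (camera adjusted p = 0.00294; adjusted p = 0.129 with an estimated correlation), and Cd22 had a ratio of 24.2 (95% counting interval 6.36 to 205). Endothelial and mesenchymal genes gave 2 that rose of 5, or 2 adjusted over the list alone (camera adjusted p = 0.0208; adjusted p = 0.124 with an estimated correlation). Mx1, an antiviral GTPase, had a ratio of 27.0 (95% counting interval 7.13 to 228), and 18 of 28 Interferon response genes rose with none falling (22 adjusted over the list alone; camera adjusted p = 5.74e-16; adjusted p = 0.0172 with an estimated correlation). The class I gene H2-K1 rose by 3.55 ± 0.16 and B2m, its partner chain, by 1.21 ± 0.14. Of 17 MHC class I region genes 7 rose and none fell (8 adjusted over the list alone; camera adjusted p = 3.16e-08; adjusted p = 0.0419 with an estimated correlation). Reads of H2-Q, H2-T, Gbp and Trim30 family members can be split between near-identical copies, so values of single members are uncertain. Benjamini-Hochberg adjusted p in edgeR's quasi-likelihood test reached at most 0.00443 (Krt8) among these genes.

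In B6, 1159 of 11409 genes tested passed an adjusted p of 0.05, 786 higher and 373 lower in whole thymocytes, and 380 were over 4-fold higher against 7 over 4-fold lower. Smaller shifts were called in the Glycolysis genes, where 3 of 17 rose and 0 fell, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.0159; adjusted p = 0.124 with an estimated correlation), and in the Cytosolic ribosomal protein genes, where 5 of 30 rose and 0 fell, or 14 and 0 adjusted over the list alone (camera adjusted p = 0.000285; adjusted p = 0.172 with an estimated correlation). Rpl3 rose by 0.75 ± 0.10 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.00104). None of the 26 Cell cycle genes passed (camera adjusted p = 0.729). The count of 1159 and its excess of higher genes depended on single libraries. There were 416 genes without B6 DP replicate 1 (349 higher and 67 lower), 486 without B6 DP replicate 2 (414 and 72), 378 without B6 whole thymocyte replicate 1 (333 and 45) and 450 without B6 whole thymocyte replicate 2 (383 and 67). There were 2190 without BALB DP replicate 1 (1250 and 940) and 2201 without BALB DP replicate 2 (1257 and 944). The excess was small without both libraries that stood apart, 2809 genes (1494 and 1315), and with only the 4 libraries compared, 2568 genes (1330 and 1238).

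The same comparison was made within BALB. Wdfy4, a gene of antigen-presenting cells, was at least 135-fold higher in whole than in DP thymocytes, Il2rb at least 124-fold higher, Eomes, a transcription factor of memory-like CD8 and natural killer cells, at least 84.7-fold higher, and Zbtb7b at least 74.9-fold higher. Zbtb16 had a ratio of 124 (95% counting interval 33.8 to 1026) between whole and DP libraries, and S1pr1 of 209 (95% counting interval 37.2 to 8314). Gimap4 rose by 5.91 ± 0.22, Cd69 by 1.36 ± 0.16, Cd5 by 0.76 ± 0.11 and Itm2a by 2.84 ± 0.16. Of 21 Mature thymocyte and egress genes 17 rose, or 17 with 1 lower adjusted over the list alone (camera adjusted p = 2.46e-35; adjusted p = 0.0445 with an estimated correlation). Of 18 TCR signal and positive selection genes 14 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 5.60e-19; adjusted p = 0.0556 with an estimated correlation). Genes of the DP stage fell, with Rag1 at −0.52 ± 0.076, Arpp21 at −0.62 ± 0.076 and Tcf12, a factor of early T cells, at −0.58 ± 0.088, and 15 of 20 DP thymocyte genes fell with none rising (16 adjusted over the list alone; camera adjusted p = 1.98e-07; adjusted p = 0.0867 with an estimated correlation). Jun changed by −4.26 ± 0.23 and Fos, its partner in the AP-1 factor, by −1.95 ± 0.30, among 15 Immediate early genes of which 7 fell and 2 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.00359; adjusted p = 0.0867 with an estimated correlation). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment the largest adjusted p of these genes was 0.00111 (Fos).

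The lineage lists were called upward in BALB whole thymocytes, and the calls of all 7 were lost with an estimated correlation. Of 13 Regulatory T cell genes 11 rose (12 adjusted over the list alone; camera adjusted p = 2.47e-14; adjusted p = 0.0556 with an estimated correlation), of 14 Innate-like NKT cell genes 11 (also adjusted over the list alone; 4.54e-12; adjusted p = 0.0867 with an estimated correlation), of 15 IL-4 response and memory-like CD8 genes 10 (also adjusted over the list alone; 1.60e-11; adjusted p = 0.105 with an estimated correlation) and of 9 CD8 lineage genes 6, with 2 lower (also adjusted over the list alone; 1.86e-06; adjusted p = 0.105 with an estimated correlation). The CD4 lineage genes held 5 higher and 2 lower of 9 (also adjusted over the list alone; 1.54e-06; adjusted p = 0.0867 with an estimated correlation), the Gamma-delta T cell genes 4 higher and 1 lower of 7 (5 and 2 adjusted over the list alone; 0.00166; adjusted p = 0.153 with an estimated correlation), and the DN thymocyte genes 8 higher of 14 (also adjusted over the list alone; 2.76e-05; adjusted p = 0.138 with an estimated correlation). Runx3 rose by 1.96 ± 0.19, Il2ra by 4.27 ± 0.30 and Maf, a factor of innate-like and gamma-delta cells, was at least 25.8-fold higher. Among non-thymocyte lists, 18 of 22 Myeloid and dendritic cell genes rose (20 adjusted over the list alone; camera adjusted p = 2.46e-35; adjusted p = 0.0445 with an estimated correlation), 9 of 11 Thymic epithelial cell genes (11 adjusted over the list alone; 1.53e-12; adjusted p = 0.0867 with an estimated correlation) and 7 of 9 B cell genes (also adjusted over the list alone; 0.000556; adjusted p = 0.153 with an estimated correlation). Cd74 rose by 4.93 ± 0.25, Krt18 by 4.04 ± 0.52 and Prss16, a protease of cortical epithelium, was at least 124-fold higher. Of 28 Interferon response genes 22 rose (24 adjusted over the list alone; camera adjusted p = 2.55e-17; adjusted p = 0.0445 with an estimated correlation) and of 17 MHC class I region genes 9 (11 adjusted over the list alone; 7.93e-08; adjusted p = 0.0867 with an estimated correlation), with H2-K1 up by 2.60 ± 0.17. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment no gene named here had an adjusted p above 0.000301 (Krt18).

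Cell cycle genes were lower in BALB whole than in BALB DP thymocytes. The proliferation marker Mki67 went from 4786 ± 642 to 3249.9 ± 127 CPM, −0.67 ± 0.10, the centromere gene Cenpf changed by −0.74 ± 0.11, the topoisomerase Top2a by −0.61 ± 0.10 and the ribonucleotide reductase subunit Rrm2 by −0.84 ± 0.13. Of 26 Cell cycle genes 19 fell, none rose and 7 did not pass (24 fell adjusted over the list alone; camera adjusted p = 1.86e-10; adjusted p = 0.144 with an estimated correlation). BALB DP replicate 1, with the highest histone share (2.52%, against 1.97% in replicate 2) and the lowest Rn45s share (3.14%), is 1 of the 2 DP libraries here. Without it the median of the Cell cycle genes was −0.41. The sex-linked Xist and Eif2s3y also differed, by 8.71 ± 1.57 and −4.20 ± 0.53, and BALB whole thymocyte replicate 1 carried 12313 counts of Xist against 203 in replicate 2. Xist overlaps its antisense partner Tsix, which this unstranded kit cannot tell apart from it. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave these genes adjusted p up to 0.00296 (Xist).

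In BALB, 1961 genes passed, 1209 higher (61.7%) and 752 lower in whole thymocytes, and 540 were over 4-fold higher against 14 over 4-fold lower. With upper-quartile scaling 1850 genes passed, of which 72.3% were higher. Without BALB DP replicate 2 the count was 3976, with 1920 higher and 2056 lower, so the excess of higher genes turned. Without BALB whole thymocyte replicate 1 it was 1158 and without replicate 2 of that group 1040. The population effects of the 2 strains, which share no libraries, overlapped in 791 genes, 788 of them in the same direction. Of these, 603 were higher in whole thymocytes, where independent lists would share 83.3, and 185 were lower, where they would share 24.6. DP thymocytes of both strains were sorted by the same markers, so shared population effects follow in part from the sort. Log2 fold changes correlated across genes at a Pearson r of 0.811.

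**Figure D2:**
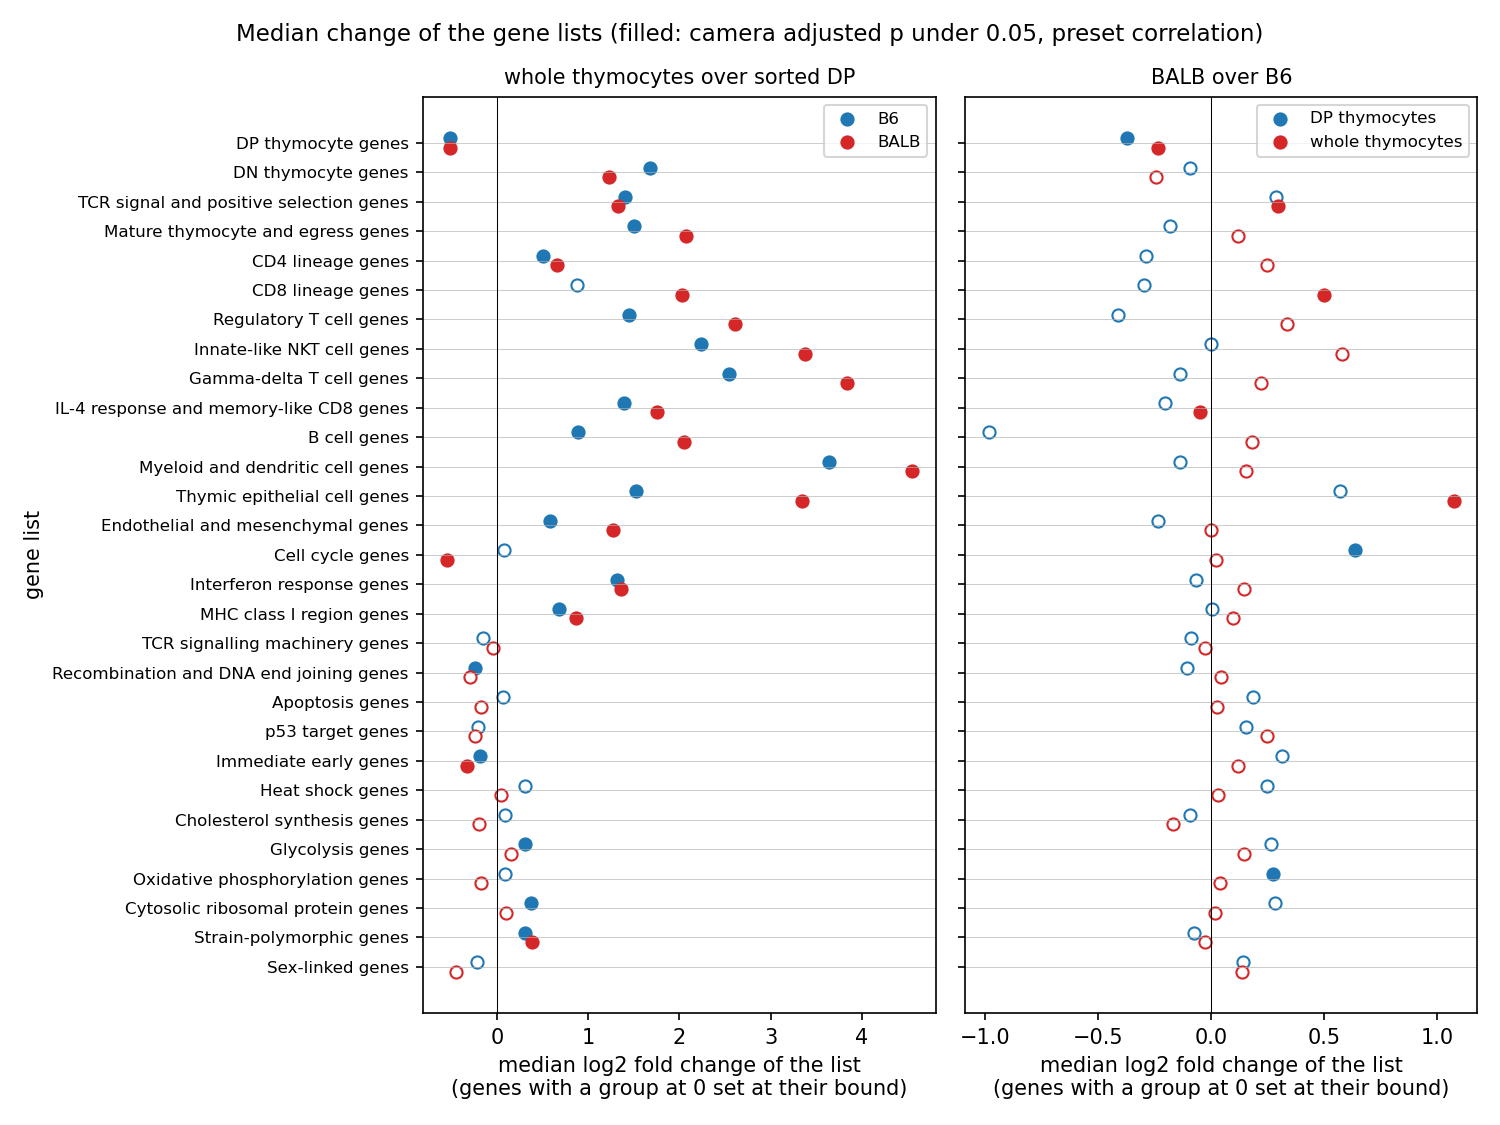
Median log2 fold change of each gene list in whole over sorted DP thymocytes (left, by strain) and in BALB over B6 (right, by population), with filled points for lists past an adjusted p of 0.05 in camera at the preset correlation and genes with a group at 0 set at their bound. Lists of mature, lineage, myeloid and interferon genes lie to the right of 0 in both strains on the left, while the IL-4 list in whole thymocytes is called upward with a median of −0.050.

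The comparison of BALB with B6 sorted DP thymocytes asks which transcripts of 1 stage differ between strains. Part of the DP thymocyte list was lower in BALB. Rag1 fell from 9842 ± 532 to 4669 ± 102 CPM, −1.08 ± 0.077, and the water channel gene Aqp11 was at −2.56 ± 0.16, the surface protein gene Ly6d at −1.92 ± 0.23 and Dntt, the polymerase that adds bases at receptor joints, at −0.67 ± 0.095. Of 20 DP thymocyte genes 10 fell, none rose and 10 did not pass (13 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.08e-08; adjusted p = 0.610 with an estimated correlation). Cd4 (−0.29 ± 0.095) and Cd8a (−0.14 ± 0.079) did not pass, at adjusted p of 0.0658 and 0.261. Several genes of receptor signalling went the other way, with Cd5 at 77.6 ± 7.34 CPM in B6 and 142 ± 18.9 in BALB, 0.87 ± 0.12, and Nr4a1 at 1.54 ± 0.24, while the costimulatory receptor Cd28, at 5.49 ± 0.00982 and 0.631 ± 0.182 CPM, was at −3.16 ± 0.53. Of 18 TCR signal and positive selection genes 4 rose and 1 fell (6 and 1 adjusted over the list alone), and camera made no call (0.179). Among 21 Mature thymocyte and egress genes 2 rose, Bcl2 among them at 1.13 ± 0.16, and 6 fell, Emb among them at −1.26 ± 0.13 (3 and 6 adjusted over the list alone; camera adjusted p = 0.483). The largest adjusted p of the genes called here, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, was 0.00219 (Cd28).

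Cell cycle genes were higher in BALB DP thymocytes. Top2a went from 1372 ± 50.8 to 2169.9 ± 239 CPM, 0.66 ± 0.10, the survivin gene Birc5 rose by 0.92 ± 0.14, the cyclin Ccna2 by 0.76 ± 0.11, Cenpf by 0.68 ± 0.11 and Mki67 by 0.56 ± 0.10. Of 26 Cell cycle genes 22 rose, none fell and 4 did not pass (23 adjusted over the list alone; camera adjusted p = 1.33e-12; adjusted p = 0.800 with an estimated correlation). BALB DP replicate 1, with the lowest Rn45s share, weighs on this list, and without it the median was 0.48. The histone share was high in both BALB DP libraries (2.52% and 1.97%). These libraries are also those in which Cell cycle genes exceeded BALB whole thymocytes, so the 2 results are not independent. Oxidative phosphorylation genes were also called higher, 5 of 25 (also adjusted over the list alone; camera adjusted p = 0.0122; adjusted p = 0.800 with an estimated correlation), but not without BALB DP replicate 1 (adjusted p = 0.127). Without B6 DP replicate 2 the call of Mki67 ended (adjusted p = 0.0640). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave the genes named here adjusted p of at most 0.00437 (Mki67) with all libraries.

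The largest strain differences were near presence against absence. Ugt8a, a lipid-modifying enzyme (chromosome 3, 125865272 to 125938682), was at least 56.6-fold higher in BALB, the guanylate-binding protein gene Gbp1 at least 32.9-fold higher, the meiosis gene Sycp1 at least 16.7-fold higher and the receptor kinase Ltk at least 16.1-fold higher. Rprl2, a ribonuclease P RNA-like gene (chromosome 3, 22251370 to 22251607) whose BALB replicates differed widely (304 ± 177 CPM), had a BALB to B6 ratio of 1002 (95% counting interval 277 to 8282). In the other direction the peptide transporter Slc15a2 was at least 254-fold lower, Trim12a (chromosome 7, 104299893 to 104315558) had a B6 to BALB ratio of 472 (95% counting interval 130.2 to 3900.4), Myzap one of 221 (95% counting interval 60.9 to 1833), and the small GTPase Rab6b changed by −5.85 ± 0.34. Pdk1, a kinase that restrains pyruvate use by mitochondria, went from 165 ± 4.50 to 34.7 ± 0.336 CPM, −2.25 ± 0.14. Among 17 MHC class I region genes 3 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.985), with H2-T3 at 4.56 ± 0.27 and H2-Q2 at −3.76 ± 0.33. The pro-apoptotic gene Bmf fell, with a log2 fold change of −1.37 ± 0.13. Rps2 (−2.82 ± 0.29) and Rps7 (−1.66 ± 0.21) fell among 30 Cytosolic ribosomal protein genes of which 2 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.483). Ribosomal protein genes have many pseudogene copies, and Trim12a, Gbp1 and the H2-Q and H2-T genes have close paralogs, so reads of 1 strain could be assigned to another copy. Adjusted p of these genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment did not exceed 0.000812 (Sycp1).

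In DP thymocytes 1482 genes passed, 781 higher and 701 lower in BALB, with 81 over 4-fold higher and 134 over 4-fold lower. The slight excess of higher genes depended on the libraries and on the fold tested. Without B6 DP replicate 1 the count was 659 (260 higher and 399 lower), without B6 DP replicate 2 it was 509 (214 and 295). Without BALB DP replicate 2 it was 3493 (1982 and 1511), and without BALB DP replicate 1 it was 1007 (495 and 512). With only the 4 libraries compared it was 562 (232 and 330). Without both libraries that stood apart it was 1399 (683 and 716). At a fold over 1.5 it was 302 (109 and 193).

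In whole thymocytes the strain comparison asks the same question across all stages. Eomes, Zbtb16 and Il2rb, genes of innate-like and memory-like T cells, were higher in BALB. Eomes was at 0.896 ± 1.27 CPM in B6 and 31.9 ± 2.11 CPM in BALB, a log2 fold change of 5.10 ± 0.53, Zbtb16 at 6.18 ± 2.84 and 31.0 ± 11 CPM, 2.30 ± 0.36, and Il2rb at 22.6 ± 3.84 and 46.7 ± 1.69 CPM, 1.02 ± 0.19. Cd44, an adhesion receptor of memory cells, rose by 1.37 ± 0.18. The cytokine gene Il4 had too few counts to be tested, with means of 0.502 CPM in B6 and 1.28 CPM in BALB. In the IL-4 response and memory-like CD8 genes 3 of 15 rose and none fell (5 and 1 adjusted over the list alone). Its median log2 fold change was −0.050 (also with genes at their bound) and its mean 0.60, and camera called it upward (0.00940; adjusted p = 0.441 with an estimated correlation). Of 14 Innate-like NKT cell genes 2 rose (5 with 1 lower adjusted over the list alone; camera adjusted p = 0.0569). Of 9 CD8 lineage genes 1, Eomes, which is also on the former list, rose, also adjusted over the list alone, with a median of 0.50 (camera adjusted p = 0.00136; adjusted p = 0.441 with an estimated correlation). The calls of both lists ended without BALB whole thymocyte replicate 1, at 0.0752 for the IL-4 response and memory-like CD8 genes and 0.0909 for the CD8 lineage genes, and the former also without B6 whole thymocyte replicate 2 (0.0844). Zbtb16 lost its call without B6 whole thymocyte replicate 2 (adjusted p = 0.0534) or BALB whole thymocyte replicate 1 (0.0514), and Il2rb without any 1 of the 4 whole thymocyte libraries (0.0520 to 0.191). With all libraries edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave the genes called here adjusted p up to 0.0128 (Il2rb).

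Thymic epithelial genes were higher in BALB whole thymocytes. Prss16 was at 12.5 ± 4.61 CPM in B6 and 46.9 ± 0.432 CPM in BALB, 1.87 ± 0.26. Of 11 Thymic epithelial cell genes 3 rose, none fell and 8 did not pass (7 rose adjusted over the list alone; camera adjusted p = 3.63e-05; adjusted p = 0.196 with an estimated correlation). DP genes were again lower, with Rag1 at −0.72 ± 0.076, Aqp11 at −3.07 ± 0.17, Ly6d at −2.43 ± 0.24 and Dntt at −0.69 ± 0.095, and of 20 DP thymocyte genes 9 fell and none rose, also adjusted over the list alone (camera adjusted p = 7.36e-11; adjusted p = 0.196 with an estimated correlation). TCR signal and positive selection genes were called upward with 1 that rose, Cd5 at 0.63 ± 0.11, and 1 that fell, Cd28 at −3.01 ± 0.57, of 18 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0394; adjusted p = 0.448 with an estimated correlation). That call ended without B6 DP replicate 1 (0.0503), B6 whole thymocyte replicate 2 (0.182), BALB whole thymocyte replicate 1 (0.0752) or replicate 2 (0.112). Cd5 lost its call without B6 whole thymocyte replicate 1 (0.0906) or 2 (0.112) or BALB whole thymocyte replicate 2 (0.0673), and Cd28 without B6 whole thymocyte replicate 1 (0.0720) or 2 (0.0719) or BALB whole thymocyte replicate 2 (0.103). Mki67 was at 0.067 ± 0.10 and did not pass (adjusted p = 0.870; interaction −0.49 ± 0.14, adjusted p = 0.253), and none of the 26 Cell cycle genes passed (camera adjusted p = 0.957). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave the called genes adjusted p of at most 0.00754 (Cd28).

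Presence against absence appeared again among single genes. H2-Ea-ps, the H2-Ea class II gene that B6 carries with a deleted promoter (chromosome 17, 34341952 to 34344645), was at least 64.6-fold higher in BALB, Ugt8a at least 45.9-fold higher and Sycp1 at least 23.3-fold higher. Gbp1 had a BALB to B6 ratio of 159.8 (95% counting interval 28.3 to 6349.7) and Rprl2 of 471 (95% counting interval 84.2 to 18656). The RNA-binding gene Rbm44 was at least 22.4-fold lower, Trim12a changed by −7.45 ± 0.31, Rab6b by −6.73 ± 0.39 and Eps8l1 by −6.24 ± 0.45. H2-K1 was lower in BALB, 176 ± 11.8 against 77.2 ± 13.3 CPM, −1.22 ± 0.13, while in DP thymocytes it was at −0.26 ± 0.20 and did not pass (interaction −0.95 ± 0.24, adjusted p = 0.194). BALB reads of this strain-variable gene may be lost where they mismatch the B6-derived reference, and their part in the difference was not tested. Among 17 MHC class I region genes 4 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.672), with H2-T3 at 3.03 ± 0.23 and H2-T10 at −2.14 ± 0.26. Cd1d2, a paralog of the antigen-presenting gene Cd1d1, rose by 1.51 ± 0.23, and Cd1d1 was at −0.12 ± 0.18 without a call (adjusted p = 0.872). Xist (9.66 ± 1.69) and Eif2s3y (−4.02 ± 0.53) were called, and replicate 1 of the BALB group carried 12313 counts of Xist, replicate 2 203, and replicate 1 none of Eif2s3y. Xist lost its call without B6 whole thymocyte replicate 1 (adjusted p = 0.0712) or 2 (0.0839). Adjusted p of the called genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment reached 0.00526 (Xist).

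In whole thymocytes 524 genes passed, 226 higher and 298 lower in BALB, with 80 over 4-fold higher and 79 over 4-fold lower. The count was 245 without B6 whole thymocyte replicate 1, 214 without replicate 2, 267 without BALB whole thymocyte replicate 1, 258 without replicate 2, 966 without BALB DP replicate 1 and 964 without BALB DP replicate 2. Without both libraries that stood apart it was 1046.

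**Figure D3:**
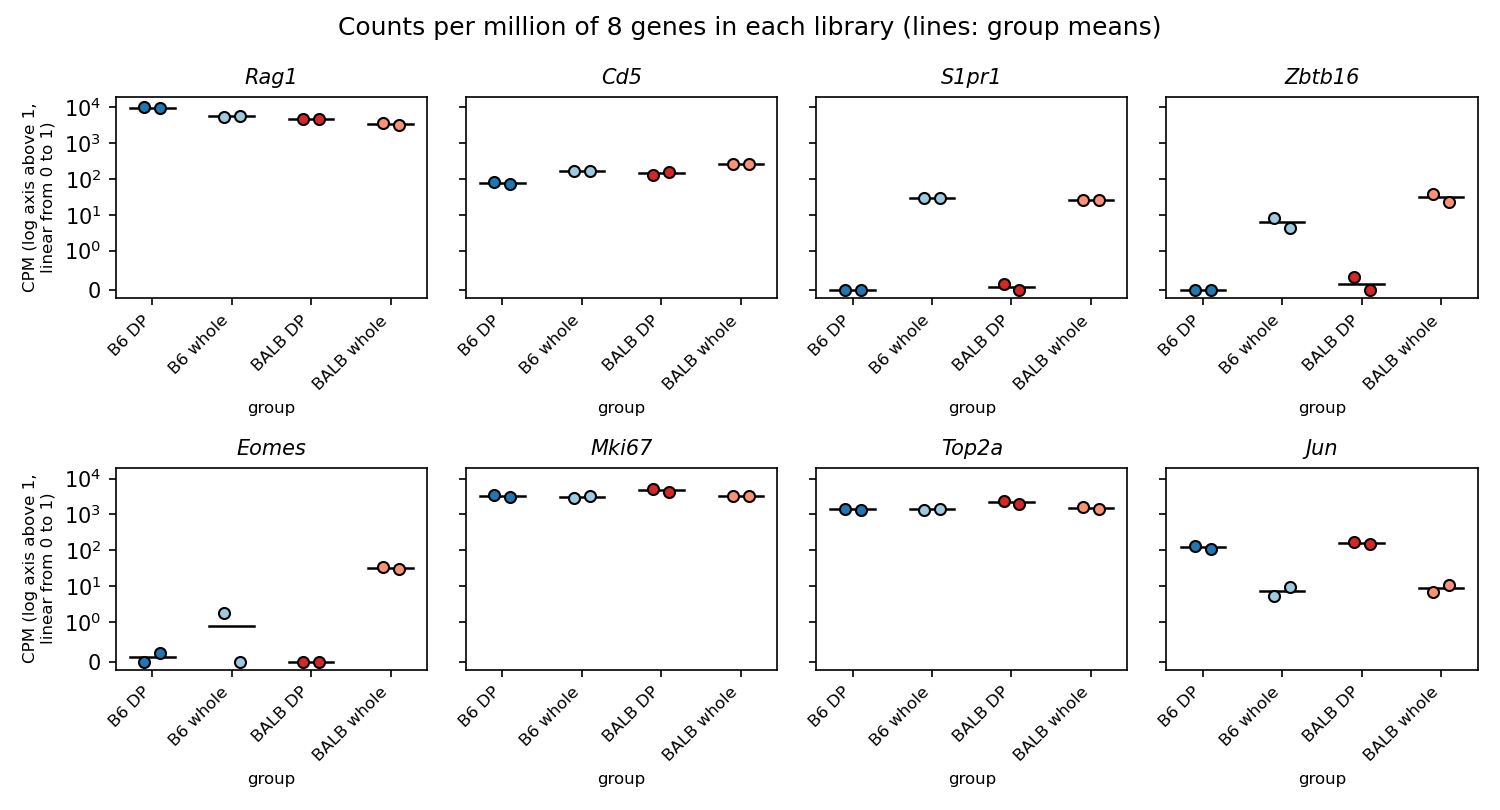
Points are CPM of 8 genes in each library and lines are group means, on an axis that is logarithmic above 1 CPM and linear below. Eomes and Zbtb16 are highest in BALB whole thymocytes (31.9 ± 2.11 and 31.0 ± 11 CPM, SD, n = 2), Mki67 and Top2a in BALB DP, and Jun is low in whole thymocytes of both strains.

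The strain effects in DP and in whole thymocytes, measured on separate libraries, overlapped in 379 genes, of which 377 went the same way. They were 127 genes higher in BALB, where independent lists would share 15.5, and 250 lower, where they would share 18.3. Of the 1482 genes called in DP thymocytes, 1263 had the same sign in whole thymocytes, and log2 fold changes correlated across genes at a Pearson r of 0.589. The overlap in the same direction, 377 genes, was 244 without B6 DP replicate 2, 207 without B6 whole thymocyte replicate 1, 182 without replicate 2 of that group, 622 without BALB DP replicate 2, 209 without BALB whole thymocyte replicate 1 and 207 without its replicate 2.

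**Figure D4:**
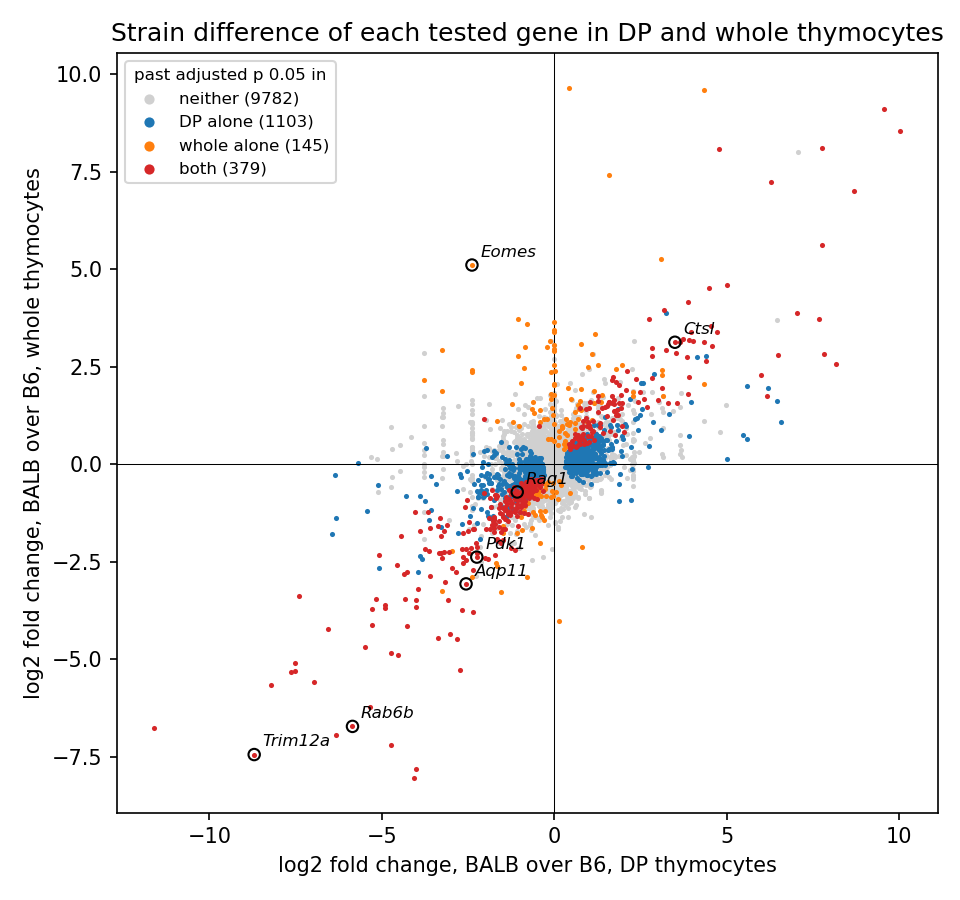
Each point is a tested gene, with its log2 fold change of BALB over B6 in DP thymocytes on the horizontal and in whole thymocytes on the vertical axis, coloured by where it passed an adjusted p of 0.05. Most of the 379 genes called in both lie near the diagonal, and fitted values of genes with a group at 0 depend on the prior count.

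Over both populations, with population as a term in the model, the genes with the smallest p included Ctsl, the cathepsin L protease (chromosome 13, 64361890 to 64370772), which rose in BALB by 3.31 ± 0.10, the collagen receptor Ddr1 by 4.80 ± 0.18, the protease Ctse by 3.08 ± 0.15 and the integrin chain Itga6 by 1.58 ± 0.079. Tdrd5 fell, with a log2 fold change of −5.11 ± 0.15, as did Nsg2 with one of −3.88 ± 0.16, Nwd1 with one of −2.51 ± 0.10 and Pdk1 with one of −2.32 ± 0.10. DP thymocyte genes fell, 10 of 20 with none rising (14 lower and 1 higher adjusted over the list alone; camera adjusted p = 3.81e-12; adjusted p = 0.0990 with an estimated correlation), and 4 of 26 Cell cycle genes rose, or 15 adjusted over the list alone (camera adjusted p = 0.00106; adjusted p = 0.981 with an estimated correlation). TCR signal and positive selection genes (5 higher and 1 lower of 18, or 8 and 1 adjusted over the list alone; camera adjusted p = 0.0484; adjusted p = 0.817 with an estimated correlation) and Thymic epithelial cell genes (6 higher of 11, or 9 with 1 lower adjusted over the list alone; 0.0337; adjusted p = 0.817 with an estimated correlation) were called upward, and each call ended without any 1 of the 4 whole thymocyte libraries (0.0562 to 0.110 and 0.0621 to 0.151). That of the TCR signal and positive selection genes also ended without B6 DP replicate 2 (0.113) or BALB DP replicate 2 (0.110). Across the comparison 1237 genes passed, 552 higher and 685 lower in BALB, and 789 without B6 DP replicate 2. Among the genes named the largest adjusted p was 1.62e-07 (Itga6) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

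Over both strains the genes with the smallest p that rose in whole thymocytes included Gimap4 by 6.22 ± 0.19, Smad7, an inhibitor of TGF-beta signals, by 6.50 ± 0.28, and Nlrc5, the transactivator of class I genes, by 3.62 ± 0.16, with the cyclin Ccnd2 at 7.66 ± 0.29 and Samhd1, a nucleotide hydrolase, at a ratio of 482 (95% counting interval 165 to 2340.4). Jun was at −4.17 ± 0.17, Glcci1 at −0.81 ± 0.060, Ppp1r15a, a stress-response phosphatase subunit, at −1.79 ± 0.16, the NF-kappa-B inhibitor Tnfaip3 at −0.81 ± 0.076 and Arpp21 at −0.61 ± 0.055. In all 2339 genes passed, 1425 higher and 914 lower, and 487 were over 4-fold higher against 8 over 4-fold lower. The largest adjusted p named was 1.95e-05 (Tnfaip3) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

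The interaction asks whether the strain difference itself differs between populations. For 12 genes BALB gained relative to B6 from DP to whole thymocytes, and for 2 it lost, a balance that turned in other settings. Pde3b, a phosphodiesterase of cyclic nucleotides (chromosome 7, 114415222 to 114537938), was at 82.2 ± 2.47 CPM in B6 DP and 21.2 ± 1.14 in BALB DP but at 116 ± 8.66 and 101 ± 0.669 in whole thymocytes, an interaction of 1.73 ± 0.17 (log2 ± SE). Cmah, the hydroxylase that makes N-glycolyl sialic acid, had an interaction of 1.80 ± 0.21, St6gal1, a sialyltransferase, of 1.71 ± 0.20, Als2cl of 1.97 ± 0.23 and Kbtbd11 of 2.92 ± 0.32. The cytoskeletal linker Dst went from 59.1 and 43.4 CPM in B6 and BALB DP thymocytes to 98.5 and 197 CPM in whole thymocytes, 1.42 ± 0.16. In each of these genes the BALB mean was below the B6 mean in DP thymocytes, and each lost its call without B6 whole thymocyte replicate 2 (adjusted p = 0.0543). None of the 26 Cell cycle genes passed alone, 22 were lower adjusted over the list alone, and the list was called with a median of −0.60 (camera adjusted p = 1.55e-20; adjusted p = 0.493 with an estimated correlation). The interaction count was 14, with 1243 genes at an unadjusted p under 0.05, 24 by DESeq2 and 8 by limma-voom. It was 8 without B6 DP replicate 1, 8 without B6 whole thymocyte replicate 1, 0 without B6 whole thymocyte replicate 2. It was 47 without BALB DP replicate 1 (22 higher and 25 lower), 1311 without BALB DP replicate 2 (384 and 927) and 139 without both libraries that stood apart (45 and 94). Without a filter it was 364 (108 and 256). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the genes named had adjusted p of 0.00502 (St6gal1) or less with all libraries.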

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

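The tests of the immediate early, cell cycle and reference-mismatch explanations in this part were chosen after the results had been seen. A difference between groups, tested as the interaction of strain and population, was found for 14 genes. Beyond the genes already described, at log2 interactions of 1.73 (Pde3b), 2.92 (Kbtbd11), 1.42 (Dst), 1.71 (St6gal1), 1.80 (Cmah) and 1.97 (Als2cl), the 2 genes in which BALB lost ground in whole thymocytes were the clone 1500009L16Rik (−3.14 ± 0.47; adjusted p = 0.0276) and the Y-linked Eif2s3y (−4.16 ± 0.67; adjusted p = 0.0408) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Eif2s3y has 0 counts in BALB whole thymocyte replicate 1, which also had 0 of Ddx3y, Kdm5d and Uty and 12313 of Xist, the pattern of female cells. It has 34 in replicate 2, where the other Y-linked genes were not low, and the cause there was not tested. Eif2s3y lost its call without any 1 of the 4 B6 libraries (adjusted p = 0.128 to 0.228) and 1500009L16Rik without any 1 library except those of BALB DP (0.104 to 0.148). Without B6 whole thymocyte replicate 2 the number of genes was 0, without BALB DP replicate 2 it was 1311, without BALB DP replicate 1 47, and without B6 DP replicate 1 or B6 whole thymocyte replicate 1 it was 8 each.

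A set of 4 gene lists also differed between populations in camera. CD8 lineage genes had a median interaction of 0.66 (adjusted p = 0.0290), Cell cycle genes of −0.60 (1.55e-20), Oxidative phosphorylation genes of −0.26 (0.00220) and Cytosolic ribosomal protein genes of −0.31 (0.00164). With an estimated correlation each had an adjusted p of 0.493, and fry called none of them. No gene of the CD8 lineage, Oxidative phosphorylation or Cytosolic ribosomal protein lists passed alone. The CD8 lineage call ended without B6 DP replicate 2 (0.0970), BALB DP replicate 1 (0.133), BALB DP replicate 2 (0.0628) or BALB whole thymocyte replicate 1 (0.117). The Oxidative phosphorylation call ended without BALB DP replicate 1 (0.0741) or BALB whole thymocyte replicate 2 (0.0600), and that of the Cytosolic ribosomal protein genes without BALB DP replicate 1 (0.133).

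Cell cycle genes higher in BALB than in B6 DP thymocytes, at a median log2 fold change of 0.64, may reflect 1 unusual library, its ribosomal RNA share, a sort that let in more dividing DN cells, or a strain difference in proliferation at the DP stage. Without BALB DP replicate 1 the median was 0.48, which argues against that library as the whole cause. With the log2 share of Rn45s as a covariate the median was 0.55 (camera adjusted p = 5.25e-14 at the preset correlation), which argues against that share as the whole cause. The covariate was fitted beside the group means, so it rests on differences between replicates, largest in BALB DP (3.14% and 6.94%). These 2 tests are therefore not independent of each other. DN thymocyte genes were at a median of 1.23 in BALB whole over BALB DP thymocytes (camera adjusted p = 2.76e-05; 8 of 14 higher; adjusted p = 0.138 with an estimated correlation), but Il2ra and others are also expressed by other cells, so whether more DN cells passed the BALB sort cannot be told. Earlier versions of 2 of these tests gave a median of −0.091 (−2.54 to 1.76) for 7 DN genes in BALB over B6 DP, which decided nothing, and 26 of 26 Cell cycle genes higher in BALB DP replicate 2 than in B6 DP replicate 2, at a median of 0.55. A strain difference in the share of dividing DP thymocytes remains a candidate explanation, with 2 libraries a side and adjusted p = 0.800 with an estimated correlation.

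Immediate early genes higher in sorted DP than in whole thymocytes could come from dilution of DP transcripts by other cells, from handling during the sort, or from regulation in DP thymocytes. The 15 tested genes of the list had a median log2 fold change of −0.18 in B6 and −0.33 in BALB, smaller than the changes of Rag1, −0.88 ± 0.076 and −0.52 ± 0.076, so dilution cannot be told apart from other causes for the list, though Jun changed by −4.08 ± 0.24 and −4.26 ± 0.23. The 4 genes called lower in both strains (Fos, Jun, Dusp1 and Klf6) had medians of −1.47 and −1.69, but they were picked by their calls, so these medians decide nothing. Whether handling raised the 4 genes cannot be told either, since the series holds no unsorted DP library and the labels do not say how whole thymocytes were handled. Fos, at −1.96 ± 0.35 in B6 (adjusted p = 0.00398), lost its call there without B6 whole thymocyte replicate 2 (adjusted p = 0.0531 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

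Strain differences over 4-fold could arise where BALB reads mismatch the B6-derived reference and are lost, or from different expression of the alleles. Of 194 genes called over 4-fold over both populations 99 were lower in BALB, or 51.0% (exact 95% interval 43.8% to 58.3%), which argues against lost BALB reads as the whole cause, since losses would lower BALB. In DP thymocytes alone 134 of 215 were lower, or 62.3% (55.5% to 68.8%), an excess to which lost reads may contribute, and in whole thymocytes 79 of 159, or 49.7% (41.7% to 57.7%). Single genes such as Trim12a, with a B6 to BALB ratio in DP thymocytes of 472 (95% counting interval 130.2 to 3900.4), may still owe their difference to sequence or copy number, and reads were not analysed here. Trim12a passed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at an adjusted p of 2.73e-09 over both populations.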

How the results depend on the processing

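Among the alternatives, leaving out chromosomes X and Y and leaving out BALB DP replicate 1 with BALB whole thymocyte replicate 1 were chosen after seeing the data. Across alternatives 3493 of 3602 values of named genes kept their side of the threshold, 104 no longer passed and 5 now passed. Many of these genes were picked by their change or p in the main fit, so this share does not speak for all called genes. With only the 4 libraries compared, 561 of the 1482 genes of strain in DP were also called, and 521 of 524 of strain in whole thymocytes. For population it was 1074 of 1159 in B6 and 1081 of 1961 in BALB. Direction was compared only where a gene passed in the main or the alternative fit. Of 1064 values of gene lists, which cover only lists called in the main fit, 956 stayed called in the same direction and 108 no longer passed. Of the 108, 55 came from the estimated correlation, under which 21 stayed called. None of these values changed direction past the threshold. Under DESeq2 size factors and upper-quartile scaling the median log2 fold change of all genes lay between −0.011 and 0.061. With 2 libraries a group, each fit without a library assumes that the lone library varies like the other groups. Depth limits what low-count genes show, and thinning to the smallest library kept every count of genes within 1.5 times.

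The numbers of genes called were 1482 for strain in DP, 524 for strain in whole thymocytes, 1159 for population in B6, 1961 for population in BALB, 14 for the interaction, 1237 for strain over both populations and 2339 for population over both strains. Testing against a fold of 1.5 with glmTreat, a stricter question by construction, they were 302, 217, 399, 687, 7, 326 and 688, and the overlap of strain calls in the same direction, 377 genes, was 154. With only the 4 libraries compared, so that the dispersion came from these alone, they were 562, 1050, 2568 and 1101 for the first 4. The counts rose for strain in whole thymocytes and population in B6, which hold no BALB DP library. They fell for strain in DP and population in BALB, which do. The order of DP and whole thymocytes, and of BALB and B6, turned, so the ranking of these counts depends on the shared dispersion. The adjusted p of single genes may likewise be too small in comparisons that hold BALB DP libraries, and too large in the others. Without a filter strain in whole thymocytes gave 839 and the interaction 364. The strict filter, which tests fewer genes, gave 325 for strain in whole thymocytes, 512 for population in B6, 910 for population in BALB, 809 for strain over both populations and 1128 for population over both strains. DESeq2's Wald test gave 748 for population in B6 and 24 for the interaction, limma-voom gave 8 and robust empirical Bayes 23 for the interaction, and the cause was not tested. Without both libraries that stood apart the counts were 1046 for strain in whole thymocytes, 2809 for population in B6 and 139 for the interaction, and the cause was not tested. With an adjusted p of 0.01 in both, 214 genes overlapped.

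Leaving out each library in turn gave 509 to 3493 genes for strain in DP, 214 to 966 for strain in whole thymocytes, 378 to 2201 for population in B6, 1040 to 3976 for population in BALB, 0 to 1311 for the interaction, 789 to 1446 for strain over both populations, 1786 to 2844 for population over both strains and 182 to 622 for the overlap of strain calls. The replicates of the BALB DP group differ most (Pearson chi-square per degree of freedom 18.3 against 1.62 to 4.35 in the other groups), and leaving out either raised the counts of population in B6 and of strain in whole thymocytes, which do not use them except for the dispersion. In the same order of 7 comparisons, 3, 5, 20, 19, 4, 4 and 21 gene lists were called, with ranges of 3 to 3, 2 to 7, 20 to 21, 20 to 21, 1 to 7, 2 to 4 and 20 to 22 without 1 library. With an estimated correlation 0, 0, 10, 3, 0, 0 and 8 lists were called. With fry 3 lists were called for strain in whole thymocytes and 0 for the interaction.

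Deviations of replicates with the same number were nearly uncorrelated between groups (−0.038 to 0.057 over 6 pairs), so the replicate numbers show no pairing of libraries. With the replicate block the counts of genes were 1321, 465, 1033, 1777, 11, 1083 and 2169, the list counts 3, 6, 20, 20, 5, 3 and 21, and the overlap 348.

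Without both libraries that stood apart, list calls ended for Oxidative phosphorylation genes in strain in DP (0.126), CD8 lineage genes (0.131) and IL-4 response and memory-like CD8 genes (0.125) in strain in whole thymocytes, CD8 lineage genes in the interaction (0.358), Immediate early genes (0.0701) and Gamma-delta T cell genes (0.0699) in the population comparison of B6, and for CD8 lineage genes (0.0626) and Gamma-delta T cell genes (0.110) in that of BALB, and for CD8 lineage genes and Cell cycle genes (0.0953 each) in population over both strains.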

Other observations

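The tests of neighbouring genes and of other splits in this part were set out before their results were seen, and the genes and lists described first were fixed before the data were examined. Components of T cell receptor signalling differed between the strains in DP thymocytes in both directions. The adaptor Pag1 was at −0.81 ± 0.10 and the phosphatase Ptpn22 at −0.91 ± 0.12 in BALB over B6, while the CD3 chain Cd3g rose by 1.01 ± 0.19. Of 23 TCR signalling machinery genes 2 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.559). Of 11 Heat shock genes 4 rose, Hsp90aa1 among them at 0.96 ± 0.20, and 2 fell, Hspa8 among them at −0.63 ± 0.14 (4 and 3 adjusted over the list alone; 0.546). Of 20 Cholesterol synthesis genes 1 rose (none adjusted over the list alone; 0.949), of 20 Apoptosis genes 1 rose, Bcl2, and 1 fell, Bmf (2 and 1 adjusted over the list alone; 0.559), and none of 16 p53 target genes passed (0.559). The nucleic acid sensor Ifi203 rose by 1.42 ± 0.15 and Ifi204, its neighbour in a family of close copies, was at least 18.0-fold higher, 2 of the 16 Strain-polymorphic genes, of which 2 rose and 2 fell (3 and 2 adjusted over the list alone; 0.546). Nnt (−0.059 ± 0.12) and Prkdc (−0.10 ± 0.12), which carry known variants in some B6 and BALB substrains, did not pass (adjusted p = 0.787 and 0.634). edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave at most 0.0153 (Hspa8) for the genes named with values. Cd3g lost its call without B6 DP replicate 1 (0.0503), Hspa8 without it (0.167), and Hsp90aa1 without B6 DP replicate 2 (0.0959).

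In the comparison of whole with DP thymocytes, the natural killer receptor genes Klrk1 and Klrd1 were at least 8.68-fold higher and at least 5.27-fold higher in B6 and at least 18.0-fold higher and at least 9.15-fold higher in BALB, the only 2 NK receptor complex genes tested, so that list has no camera test. The beta-globin gene Hbb-bs, listed as Beta-s, rose by 2.95 ± 0.57 in B6 and 4.47 ± 0.59 in BALB, 1 of 3 Erythroid genes tested, which also have no camera test. Strain-polymorphic genes, which include the mature thymocyte gene Ly6a and the receptor gene Slamf7, were called upward in B6 (6 higher and 1 lower of 16; camera adjusted p = 0.00877; adjusted p = 0.124 with an estimated correlation), and Slamf7 had a ratio of 58.6 (95% counting interval 10.1 to 2349). IL-4 response and memory-like CD8 genes rose in B6 whole thymocytes, 6 of 15 with 1 lower (7 and 2 adjusted over the list alone; median 2.27, or 1.39 with genes at their bound; 2.34e-07; adjusted p = 0.0765 with an estimated correlation). The chaperonin gene Hspd1 rose by 0.72 ± 0.12 in B6 and 0.62 ± 0.12 in BALB, and the ubiquitin ligase Cbl was at −0.51 ± 0.081 and −0.37 ± 0.081. In B6, Klrk1 lost its call without B6 DP replicate 2 (adjusted p = 0.0749) or B6 whole thymocyte replicate 1 (0.0652), Klrd1 without any 1 of the 4 B6 libraries (0.0872 to 0.133), Hbb-bs without B6 DP replicate 1 (0.0608) or B6 whole thymocyte replicate 2 (0.0587) and Hspd1 without B6 DP replicate 2 (0.0567), and in BALB Cbl without BALB whole thymocyte replicate 1 (0.0560) and Klrd1 without both libraries that stood apart (0.0879). Largest adjusted p among these genes, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, was 0.0191 (Klrd1).

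Sex-linked transcripts departed in the 2 BALB whole thymocyte libraries, and not alike in both. Replicate 1 had 12313 counts of Xist (3115 CPM) and none of Ddx3y, Kdm5d, Uty or Eif2s3y, and replicate 2 had 203 counts of Xist (52.3 CPM) with 34 counts of Eif2s3y (8.76 CPM against 63.6 to 80.3 CPM in the 6 other libraries). Its other Y-linked genes were not low, with Ddx3y at 187 CPM (115 to 197 in the 6 other libraries), Kdm5d at 99.5 CPM (93.1 to 127) and Uty at 73.7 CPM (70.3 to 101). In the other 6 libraries Xist had 6 to 24 counts. Of 9 Sex-linked genes in the strain comparison of whole thymocytes 1 rose and 1 fell, also adjusted over the list alone, with a median of 0.13, a mean of 0.48 and a downward camera test (0.821). The labels give no sex. Replicate 1, with Xist and without Y-linked counts, has the pattern of female cells, while every other library held Y-linked counts. Differences of Xist and Y-linked genes in comparisons with this library can therefore come from sex and not from strain or population.

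Genes called between strains may lie in inherited blocks in which the strains differ at several genes. Of 11349 tested genes with a position 1231 were called over both populations, and 245 pairs of neighbouring tested genes were both called, where a permutation test of 10000 random placements gave a mean of 133 (95% range 113 to 154; ratio 1.84; p = 1e-04, the smallest these placements can give). For genes called between populations there were 598 pairs against a permutation mean of 477 (444 to 511; ratio 1.25; p = 1e-04, again the smallest), so some of the clustering is not particular to strain. Among strain calls over 2-fold, 484 genes, there were 58 pairs against 20.6 (13 to 29; ratio 2.82). The ratio depends on how many genes are called, so the ratios are not directly comparable. The windows of 20 tested genes with the most calls, 10 each, start at 16810909 on chromosome 12, with Rock2, Adam17 and Klf11, and at 100798759 on chromosome 5, with Aff1 and the Gbp genes Gbp4 and Gbp6, and were picked after their values were seen. These values fit the hypothesis by the rule set beforehand, which asked for more pairs than random placements gave and a higher ratio than for population calls. With 1231 strain calls against 2330 population calls, the higher ratio does not show that strain calls cluster more. Overlapping genes, shared regulation and paralogous reads, as in the Gbp cluster, could add to the pairs.

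All 35 splits of the 8 libraries into 4 and 4 were compared with the real groupings. For strain over both populations the real split gave 1237 genes, and 2 of 35 splits gave as many, the real one and the split by population with 1402. The latter is the other factor of the design and was fitted without a population term, so its count is not directly comparable. The share of splits alone therefore cannot exclude chance or decide about it, since 1 of the 2 splits is that other factor. Strain calls in DP and in whole thymocytes, made on separate libraries, shared 379 genes, 377 of them in the same direction. This argues against chance for those shared genes. For population over both strains the real split gave 2339, 1 of 35 splits gave as many, and the highest other was 525, from the split by strain. The remaining 33 splits gave 0 genes each in both cases.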
